A study of Oreochromis niloticus with 12 samples.

How the data were processed

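Messenger RNA of whole brains and pituitaries was sequenced in mature male Nile tilapia of dominant or subordinate status, with 3 samples for each of 4 groups. Samples were grouped by the tissue and the hierarchical status in the labels, and replicate numbers were taken from the titles. Per the labels' protocols, each tank held 2 males and several females, males were dye-marked and watched for 14 days, total RNA was extracted with a miRNeasy kit, and libraries were made with a TruSeq RNA v2 kit. Per the submitters' processing notes, the authors used FastQC 0.11.4, Trim Galore, STAR 2.201, HTSeq, DESeq2 and DESeq. The genome build, the annotation, the strand setting and the treatment of reads that match several loci are not given in the sources used here. Transcripts of near-identical loci may therefore share reads. Whether the pair named lnpk is such a case was not tested.

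The deposited signal values are named normalised read counts. That the gene counts of each library were divided by a size factor is inferred from the values. In every column 100% of values were whole multiples of a single step, within a tolerance of 0.01 reads, so the whole counts behind the authors' deposited values could be recovered together with size factors of 0.956 to 1.10 in the brain and 0.802 to 1.53 in the pituitary. Brain libraries held 23733115 to 26867631 recovered reads. The authors' deposited log2 fold changes and p-values, per the file headers, compare dominant with subordinate males and are not adjusted. The brain table held 27115 genes after 251 blank lines were left out. The pituitary table held 714 genes, all with an authors' deposited p-value under 0.05 (highest 0.0499), and so is a selection by outcome. Its 714 genes do not give the depth of the pituitary libraries, and how precisely genes outside them were measured is unknown. Both tissues were normalised separately and were tested separately. There were 0 columns of values that were not used.

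Gene names were taken from the files or, for identifiers that begin with LOC, from a RefSeq gene table of assembly O_niloticus_UMD_NMBU, which matched 17128 of 17130 such identifiers in the brain and 368 of 368 in the pituitary and gave a symbol to 5834 and 195. As the build behind the files is not stated, no positions are printed, and that table was used only for names and for which genes neighbour each other.

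The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with eBayes and trend=TRUE, over genes with a mean of at least 10 normalised reads, and an adjusted p under 0.05 (Benjamini-Hochberg, two-sided) was called. A fold change on this scale understates the change of low genes. An exact permutation test of 3 against 3 samples cannot give a p under 0.1. Gene lists (30, fixed before the data were examined) were tested in the brain with camera at a preset correlation of 0.01, and then with an estimated correlation and with fry. They were not tested in the pituitary, because a competitive test needs the unchanged genes. Named genes followed a rule fixed before the data were examined. Per tissue it took up to 12 called, named genes per direction with groups that do not overlap, filled up to 8 per direction by smallest p, all members of the hormone and reproductive neuropeptide lists, up to 4 called members of other lists, and up to 10 genes called in both tissues. Called genes without a usable name numbered 5 in the brain and 3 in the pituitary. Differences between tissues were tested as the difference of both limma estimates over its standard error, which takes the tissues as independent.

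The brain test was tested on simulated data with 21489 genes drawn from the real means. It recovered 52 of 98 genes changed 2-fold (53.1%) and 81 of 99 changed 4-fold (81.8%), with 6 false calls. It also found a shifted list and called 0 of 50 random lists. The simulated genes were drawn independently of each other, so the list result does not cover real lists whose members vary together. The estimated correlation ran from 0.033 to 0.91 over the lists that passed at the preset correlation.

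Alternatives were other pseudocounts (0.5 and 5), other filters (none, or a mean of at least 50), TMM and quantile rescaling, the replicate number as a block, each replicate left out, robust limma, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and other thresholds. On these reads edgeR called 6 genes in each tissue, the 6 called by limma, and DESeq2 called 84 in the brain and 190 in the pituitary. A covariate made of the mean log2 value of hox genes of paralog groups 5 and above, and Benjamini-Hochberg adjustment of the authors' deposited p-values, were added after the data were seen. So was limma on pituitary minus brain log2 values with samples of the same number and status paired. Figures were drawn with matplotlib 3.10.9.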

Results

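Gene expression was measured by RNA sequencing in the brain and the pituitary of mature male Nile tilapia (Oreochromis niloticus), a cichlid in which males form dominance hierarchies. Males had been housed 2 per tank with females, and tissues were taken on day 14 from dominant, reproducing males and from subordinate, non-reproducing males. There were 3 libraries per tissue and status, 12 in all. Brain libraries held 23733115 to 26867631 recovered reads over 27115 genes. Of these genes 21743 had a mean of at least 10 normalised reads and were tested. The deposited pituitary table held 714 genes, and each of them had a p-value under 0.05 in the authors' deposited table of the same comparison. The reads in these 714 genes, 1649554 to 7025630 per library, are therefore not library depths. Values below are normalised read counts given as mean ± SD (n = 3). Differences are dominant minus subordinate on the log2(value + 1) scale with a standard error (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless a list test is named. The labels do not say whether the numbered samples came from separate tanks, so the p-values of single genes measure the spread between these samples. List p-values from camera at its preset correlation take the genes of a list as almost unrelated. Those list p-values do not measure how a list as a whole varies between the samples.

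The first comparison asked which brain transcripts differ with social status. The transcript lnpk, whose product lunapark holds junctions of the endoplasmic reticulum in place, was higher in dominant brains. It stood at 402 ± 36.0 against 180 ± 7.98 normalised reads, a log2 difference of 1.15 ± 0.10 (SE, adjusted p = 0.0380). It is the locus that the table itself names lnpk. A separate locus to which the reference gives the same name, LOC100690971, did not differ, at 1042 ± 42.5 against 1042 ± 37.9. The 5 other genes that passed the test carried no name in the table or the reference, and all 5 were also higher in dominant brains. Among them LOC100703972 stood at 549 ± 15.7 against 46.6 ± 5.94 (adjusted p = 0.000565) and LOC100712056 at 309 ± 32.7 against 1.36 ± 1.18 (adjusted p = 0.0118).

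These 6 genes were the only ones of 21743 with a limma adjusted p under 0.05. At an unadjusted p under 0.05 there were 1124 genes (5.17%), 673 higher and 451 lower. The groups did not overlap for 2346 genes (10.8%, where chance gives 10%). The count was 2, 3 and 1 without dominant replicates 1, 2 and 3, and 15, 3 and 3 without subordinate replicates 1, 2 and 3, and lnpk passed in none of these 6 fits (adjusted p = 0.0811 to 0.372). It was 84 with DESeq2 (71 higher, 13 lower) and 0 with limma when a score of posterior hox genes, described below, was a covariate (1395 genes then had an unadjusted p under 0.05).

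Among named brain genes that did not pass, those of smallest p on the higher side included enzymes of sterol synthesis. hmgcra, a form of the rate-limiting HMG-CoA reductase, stood at 547 ± 26.9 in dominant and 307 ± 32.3 in subordinate brains (log2 difference 0.83, adjusted p = 0.16). cyp51, the lanosterol demethylase, stood at 702 ± 34.6 and 449 ± 25.8 (0.64, adjusted p = 0.16). msmo1, a sterol-4-alpha-methyl oxidase, stood at 555 ± 80.2 and 310 ± 20.5 (0.83, adjusted p = 0.340). The others on the higher side included pkd1b, a polycystin family member (111 ± 14.5 and 32.1 ± 4.44), and sft2d2b, of vesicle transport (226 ± 36.7 and 106 ± 1.98). They also included rfc4, a subunit of the DNA clamp loader (205 ± 10.3 and 111 ± 11.2), and b3gnt5a, a glycosyltransferase (52.5 ± 4.17 and 2.19 ± 2.28). Adjusted p ran from 0.119 to 0.355 over these 4. On the lower side the genes of smallest p were postna, a periostin of the extracellular matrix (144 ± 4.95 and 247 ± 26.8), npy8br, a neuropeptide Y receptor (692 ± 88.3 and 1081 ± 61.1), and bhlhe22, a neuronal transcription factor (1536 ± 145 and 2263 ± 218). eomesa, a T-box factor of the forebrain, stood at 2198 ± 331 and 3584 ± 553, and kcnh3, a potassium channel, at 1060 ± 119 and 1559 ± 200. The remaining 3 were senp7b, a SUMO protease (826 ± 121 and 1182 ± 40.7), bco2a, which cleaves carotenoids (674 ± 61.2 and 908 ± 70.5), and b3gat1b, a glucuronyltransferase (1549 ± 112 and 2101 ± 226). Adjusted p ran from 0.389 to 0.828 over these 8. In each of the 15 named genes that did not pass, the 3 dominant and 3 subordinate values did not overlap. Choosing genes by smallest p favours this, so it adds no support. Of these genes rfc4, b3gnt5a and senp7b lie in the dense run of neighbouring genes described below, where inherited haplotypes are a candidate. They may therefore not be separate signals.

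Genes for cholesterol synthesis and uptake were higher in dominant brains as a group. Of 29 tested members of this list, fixed before the data were examined, 26 were higher, with a median log2 difference of 0.28. The list passed limma's camera test with its preset correlation (adjusted p = 4.24e-15 over 30 lists). The call was lost with the correlation estimated from the 6 libraries (adjusted p = 0.302 with an estimated correlation). No member passed over all genes, while 7 did when adjusted over the list alone by limma. Among these were hmgcra, cyp51, msmo1, sqle, acat2 and nsdhl. The gene sqle, which makes squalene epoxide, stood at 207 ± 12.2 against 115 ± 18.7 (log2 difference 0.85, limma adjusted p = 0.00574 over the list alone). The transcripts of srebf1 and srebf2, the transcription factors of this pathway, differed by 0.02 and -0.04.

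**Figure D1:**
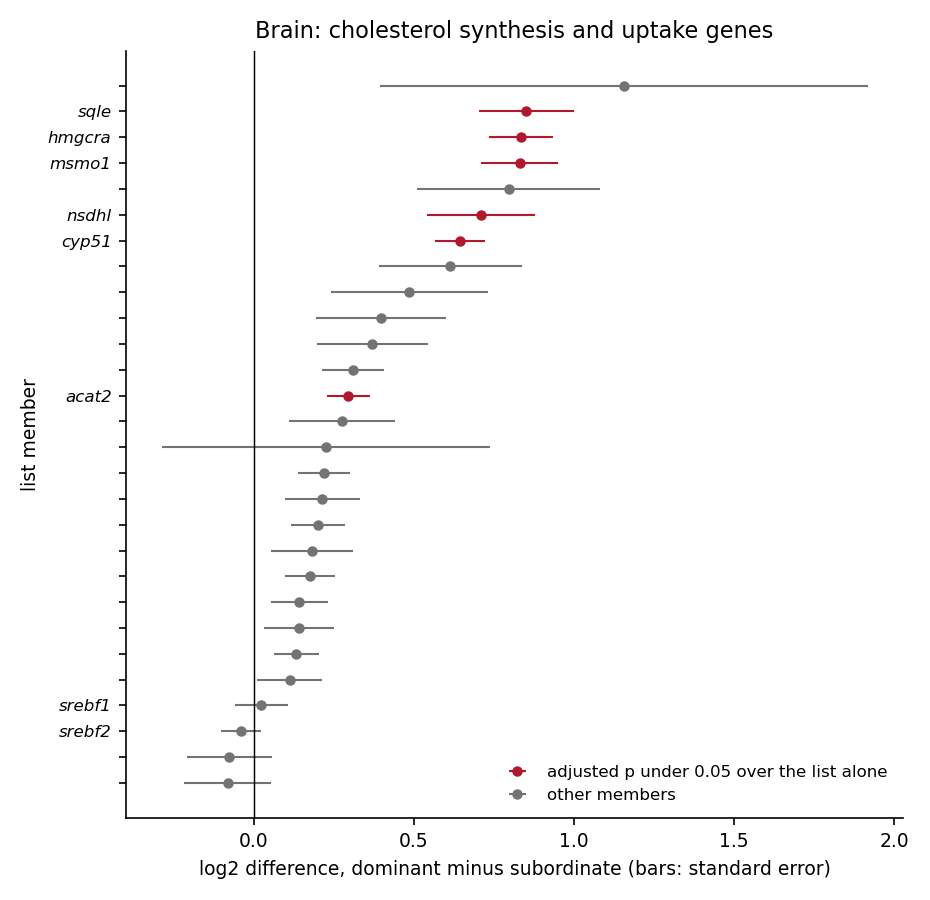
Log2 difference in the brain (dominant minus subordinate, horizontal axis) for 28 of the 29 tested genes of cholesterol synthesis and uptake (vertical axis, names given for those in the text), with bars of 1 standard error from limma over 3 against 3 libraries. Red points mark 6 of the 7 genes that passed when p was adjusted over the list alone, the other is not shown, and 25 of the 28 points lie above 0.

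Myelin genes were higher in dominant brains in 19 of 21 members, with a median log2 difference of 0.30 (camera adjusted p = 2.49e-06, and adjusted p = 0.468 with an estimated correlation). The median was 0.115 without subordinate replicate 3 and 0.457 without subordinate replicate 1, and the list passed in each left-out fit. No member passed over all genes or adjusted over the list alone by limma, and 6 had an unadjusted p under 0.05. fa2h, which hydroxylates the fatty acids of myelin lipids, stood at 1086 ± 164 against 700 ± 141. ugt8, which makes galactosylceramide, stood at 1501 ± 54.6 against 1102 ± 244, and myrf, a regulator of myelin genes, at 2333 ± 45.5 against 1895 ± 249. Posterior hox genes, whose products pattern the hindbrain and spinal cord, were in no fixed list and were chosen after their values were seen. Of 11 hox genes of paralog groups 5 to 9, all 11 were higher with a median log2 difference of 2.91, 8 had groups that did not overlap, and 0 passed limma's test over all genes (8 had an unadjusted p under 0.05). The 11 hox genes of groups 1 to 4 were also all higher, with a median of 0.633. For 9 of them the groups overlapped, and 0 passed limma's test (4 had an unadjusted p under 0.05). hoxc8 stood at 81.9, 132 and 79.5 reads in the 3 dominant brains and at 10.9, 0 and 0 in the subordinate ones. The mean log2 value of these 11 genes was 6.32 to 7.14 in dominant brains and 5.39, 1.69 and 2.67 in subordinate brains 1, 2 and 3. With that score as a covariate the myelin median was 0.0050 (camera adjusted p = 0.988) and the cholesterol median was 0.16 (camera adjusted p = 0.00117).

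**Figure D2:**
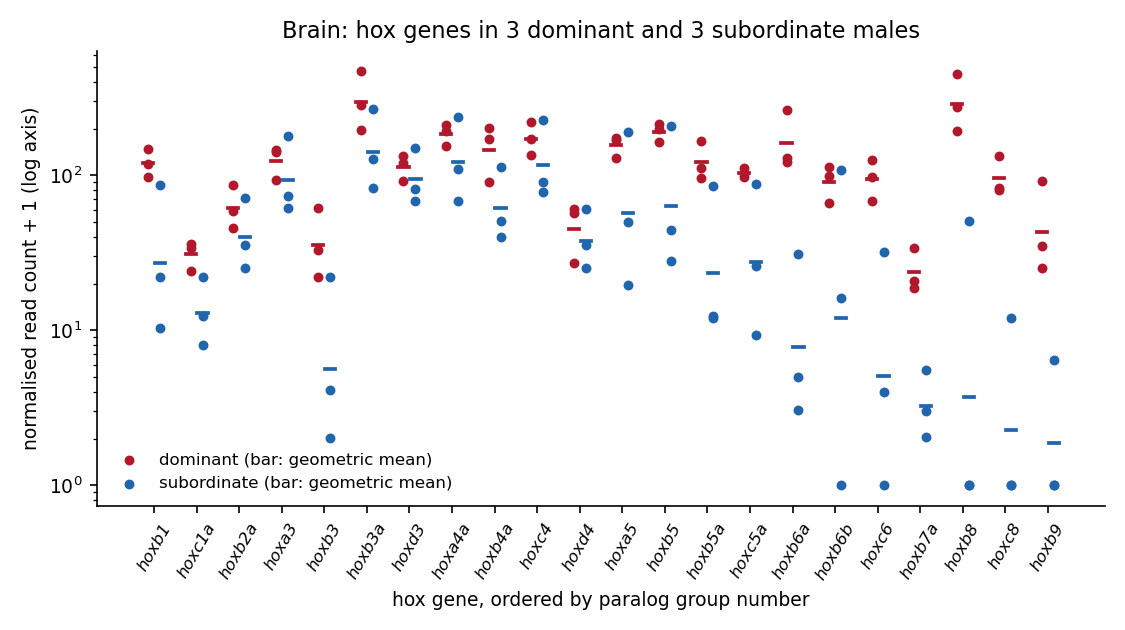
Normalised read count plus 1 (vertical log axis) of the 22 tested hox genes in the brain, ordered by paralog group number, for 3 dominant (red) and 3 subordinate (blue) males, with a bar at each geometric mean. In hoxc8 the dominant values run from 79.5 to 132, and 2 of the subordinate values are 0.

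Genes of antiviral defence and antigen presentation were higher in dominant brains in 23 of 24 members, with a median of 0.35 (camera adjusted p = 1.6e-08, and adjusted p = 0.468 with an estimated correlation). The median was 0.204 without subordinate replicate 3, and the list passed in each left-out fit. nlrc5, a regulator of antigen presentation genes, stood at 177 ± 15.8 against 105 ± 32.3. Radial glia and astrocyte genes were higher in 11 of 17 members (median 0.25, camera adjusted p = 0.0166, and adjusted p = 0.468 with an estimated correlation). Among them gfap, the glial intermediate filament, stood at 20179 ± 3339 against 14396 ± 993 and fabp7a, a fatty acid carrier of radial glia, at 2925 ± 591 against 1970 ± 252. Fibroblast and matrix genes were higher in 29 of 39 (median 0.13, camera adjusted p = 0.0179, and adjusted p = 0.468 with an estimated correlation). The 1 member of that list to pass when adjusted over the list alone, postna, was lower, while col1a1 stood at 301 ± 34.1 against 201 ± 58.9. Cell cycle genes were higher in 28 of 35 (median 0.23, camera adjusted p = 0.00383, and adjusted p = 0.767 with an estimated correlation). Microglia and macrophage genes were higher in 13 of 15 (median 0.17, camera adjusted p = 0.0229, and adjusted p = 0.767 with an estimated correlation). Cytoplasmic ribosomal proteins were higher in 77 of 85 (median 0.047, camera adjusted p = 0.00383, and adjusted p = 0.775 with an estimated correlation). With 1 sample left out at a time, some of these calls were lost. The radial glia call was lost without dominant replicate 2 (median 0.177) and subordinate replicate 1 (0.0692), and the matrix call without dominant replicate 3 (0.134) and subordinate replicate 2 (0.0918). The cell cycle call was lost without dominant replicates 1 and 2 (0.0842 and 0.153) and subordinate replicates 2 and 3 (0.093 and 0.136), and its median was 0.402 without subordinate replicate 1. The microglia call was lost without dominant replicates 2 and 3 (0.0808 and 0.253) and subordinate replicate 3 (0.0128). Its median was 0.275 without dominant replicate 1, and 0.457 and 0.249 without subordinate replicates 1 and 2. The ribosomal call was lost without dominant replicate 2 (-0.0115) and subordinate replicates 1 and 3 (0.0246 and 0.035), and its median was 0.0806 without dominant replicate 1 and 0.0785 without subordinate replicate 2. With the hox score above as a covariate, the radial glia and ribosomal lists still passed (medians 0.29 and 0.0964, camera adjusted p = 0.0463 and 0.00879). With it, the antiviral, microglia and matrix lists no longer passed (medians 0.191, -0.304 and 0.00233, camera adjusted p = 0.109, 0.121 and 0.988), so the microglia median turned, and the cell cycle list passed on the lower side with a median of -0.39.

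Lower in dominant brains were the immediate early genes, which respond to neuronal activity, in 23 of 26 members (median -0.24, camera adjusted p = 0.0118, and adjusted p = 0.767 with an estimated correlation). Among them were klf2 at 694 ± 43.8 against 905 ± 176 and junbb at 1738 ± 466 against 2375 ± 715. Genes of oxidative phosphorylation were lower in 68 of 95 (median -0.038, camera adjusted p = 0.0369, and adjusted p = 0.767 with an estimated correlation). The immediate early call was lost without dominant replicate 1 (median -0.0942) and subordinate replicates 1 and 2 (-0.183 and -0.0531), and its median was -0.4 without subordinate replicate 3. The oxidative phosphorylation call was lost without dominant replicates 1, 2 and 3 (-0.0343, -0.0387 and -0.0299) and subordinate replicates 1 and 3 (-0.0161 and -0.0264). With the hox score as a covariate the oxidative phosphorylation list passed (median -0.0944, camera adjusted p = 0.00205), while the immediate early list and the pituitary hormone list below did not (-0.114 and -0.218, camera adjusted p = 0.229 and 0.681). Pituitary hormone transcripts, also detected in brain libraries, were lower in 7 of 7 members (median -0.56, camera adjusted p = 0.000509, and adjusted p = 0.548 with an estimated correlation). The median was -0.195 without subordinate replicate 3. All 7 were highest in that library, at 1.69 to 3.68 times the mean of the other 5 brains, and so was gh1 at 2.46 times. In the brain fshb stood at 115 ± 15.4 against 223 ± 104, lhb at 259 ± 38.9 against 535 ± 412, and cga at 281 ± 54.0 against 607 ± 388. The others were pomc at 5296 ± 1004 against 7801 ± 3143, prl at 2436 ± 593 against 3497 ± 1499, smtla at 774 ± 137 against 1208 ± 574, and tshba at 25.9 ± 3.99 against 32.3 ± 10.7. Over all genes none of the 7 passed by limma (adjusted p = 0.934 to 0.937).

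Reproductive neuropeptide genes were higher in dominant brains in 12 of 15 members (median 0.44, camera adjusted p = 0.00584, and adjusted p = 0.468 with an estimated correlation). No single member passed over all genes or adjusted over the list alone. With the hox score as a covariate the list did not pass and its median turned to -0.0638 (camera adjusted p = 0.988), nor did it without dominant replicate 2 (median 0.437, camera adjusted p = 0.0543). oxt, which encodes isotocin, the fish oxytocin, stood at 8937 ± 1570 against 4726 ± 1640. The 3 dominant values lay above the 3 subordinate ones (log2 difference 0.97, adjusted p = 0.895). tac3a, a neurokinin B precursor, stood at 172 ± 27.9 against 111 ± 36.1, nmu, the neuromedin U precursor, at 44.4 ± 6.08 against 24.6 ± 13.7, and vip at 217 ± 65.9 against 147 ± 60.8. The gonadotropin-releasing hormone genes had wide spreads or small differences. Those were gnrh1 at 174 ± 19.1 against 200 ± 29.7, gnrh2 at 87.0 ± 42.6 against 35.8 ± 36.7 and gnrh3 at 104 ± 93.4 against 51.2 ± 80.3. avp, which encodes vasotocin, stood at 11285 ± 4253 against 10242 ± 7198, and gal, the galanin gene, at 323 ± 67.2 against 326 ± 159. The tachykinin genes tac1 (413 ± 38.5 and 355 ± 34.0), tacr3a (48.9 ± 6.02 and 36.4 ± 9.20) and tacr3b (20.02 ± 27.5 and 24.5 ± 12.5) overlapped between groups. So did pdyn (575 ± 184 and 616 ± 105), spx (26.5 ± 3.07 and 25.03 ± 10.9) and kiss2 (16.7 ± 15.2 and 10.5 ± 6.59).

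The other 18 lists did not pass in the brain (camera adjusted p = 0.0629 to 0.896). Their median log2 differences were 0.085 for cartilage, bone and epithelium, -0.15 for pituitary receptors and transcription factors, and -0.025 for gonadotropin second messengers. They were 0.014 for glycolysis, -0.024 for circadian clock, -0.051 for retina and pineal, 0.0065 for neuron and synapse, 0.0077 for growth axis and 0.075 for lipid transport and liver-type proteins. They were 0.013 for endothelium and mural cells, -0.0089 for ion channels, 0.051 for monoamine genes, and 0.041 for thyroid axis. They were -0.030 for skeletal muscle, 0.0087 for heat shock and protein folding, -0.023 for feeding and stress neuropeptides, -0.036 for steroid receptors and metabolism, and 0.0083 for erythrocyte genes. The median, the mean and the direction given by camera differed in sign for endothelium, ion channels, skeletal muscle, heat shock, and feeding and stress neuropeptides. Adjusted over the list alone by limma, dspb (967 ± 338 against 351 ± 97.5) and acanb (492 ± 29.5 against 310 ± 51.7) of the cartilage, bone and epithelium list passed, and 0 members of the other 17 lists did. None of the 12 list calls held with an estimated correlation or with fry's directional test, and 6 of the 12 remained without dominant replicate 2.

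The second comparison asked the same question in the pituitary. The gene igfbp5, which encodes a binding protein of insulin-like growth factors, was higher in dominant pituitaries. It stood at 410 ± 177 against 46.1 ± 13.4 normalised reads, a log2 difference of 3.06 ± 0.38 (SE, adjusted p = 0.0185). lnpk stood at 819 ± 205 against 165 ± 32.5 (2.29 ± 0.25, adjusted p = 0.00963), and cdc42ep1b, an effector of the GTPase Cdc42, at 708 ± 108 against 302 ± 44.2 (1.23 ± 0.18, adjusted p = 0.0389). The 3 other genes that passed had no name, and all 3 were higher as well. They were LOC100703972 (243 ± 7.35 against 17.4 ± 6.19), LOC100701774 (165 ± 1.86 against 4.44 ± 0.617) and LOC100703705 (145 ± 17.3 against 11.7 ± 7.03).

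The pituitary table was a selection by outcome, so these 6 calls of 714 genes, and all adjusted p-values here, cover only the genes deposited and are no count over a transcriptome. When brain genes were picked in the same way, by an unadjusted DESeq2 p under 0.05, in the 9 other splits of the 6 brains, limma called 6 to 380 genes and 68.8 to 80.7% had groups that did not overlap. Those values were 6 genes and 66.0% (471 of 714) in the pituitary. The count was 0 without dominant replicate 3 (169 genes then had an unadjusted p under 0.05). It was 255 without subordinate replicate 1 (114 higher, 141 lower), while DESeq2 called 190 (127 higher, 63 lower). Of the 714 genes, 372 were higher and 342 lower.

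Both gonadotropin subunits and their shared alpha subunit had higher values in dominant pituitaries. fshb, the beta subunit of follicle-stimulating hormone, stood at 66200 ± 20456 against 22559 ± 10895 (log2 difference 1.64 ± 0.42). lhb, that of luteinising hormone, stood at 264110 ± 38707 against 120880 ± 60166 (1.24 ± 0.40), and cga, the alpha subunit, at 232900 ± 74525 against 133690 ± 35641 (0.79 ± 0.33). Groups did not overlap for any of the 3 genes. None passed over the 714 genes (limma adjusted p = 0.0855 for each). Among genes already selected by the authors' p-values, fshb and lhb passed adjusted over the list alone (p = 0.0176 and 0.0269 by limma) and cga did not (p = 0.0510). oxt stood at 87.1 ± 44.1 against 14.3 ± 11.3 (2.75 ± 0.76, limma adjusted p = 0.0855). gh1, the growth hormone gene, was outside the naming rule and was chosen after its values were seen. It stood at 1031200, 1855600 and 1323400 reads in dominant pituitaries and at 1252900, 3063200 and 5513600 in subordinate ones (log2 difference -1.02 ± 0.66, limma adjusted p = 0.174). It took 49.6 to 84.2% of the reads in the deposited rows.

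**Figure D3:**
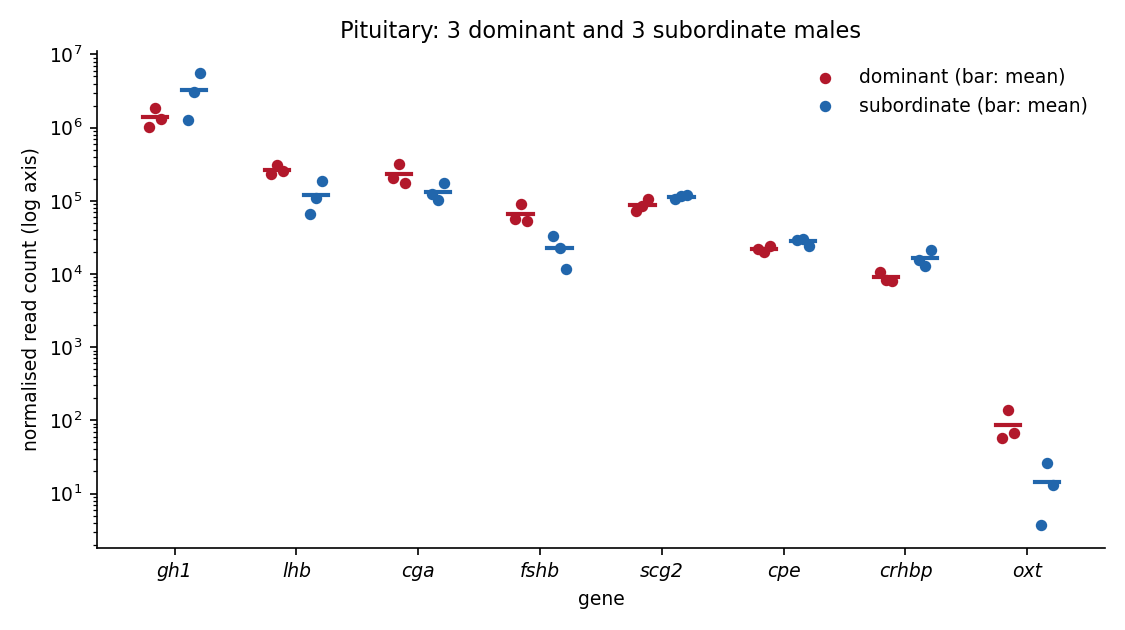
Normalised read counts (vertical log axis) of 8 pituitary transcripts in 3 dominant (red) and 3 subordinate (blue) males, with bars at the means. fshb, lhb, cga and oxt lie higher in the dominant males with no overlap, crhbp and cpe lie lower with no overlap, and gh1 and scg2 overlap.

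Other pituitary genes of smallest p did not pass over the deposited genes (limma adjusted p = 0.0760 to 0.0855). On the higher side these were cpt1b, the mitochondrial carnitine palmitoyltransferase (1052 ± 658 against 127 ± 39.7), armc3 (425 ± 75.5 against 211 ± 28.9), and hnf4a, a nuclear receptor (843 ± 156 against 452 ± 44.9). asic1c, an acid-sensing ion channel (128 ± 26.5 against 34.2 ± 13.6), and klhl5 (711 ± 220 against 326 ± 29.9) were the others on that side. On the lower side they were pnp5a, a purine nucleoside phosphorylase (69.9 ± 22.7 against 294 ± 121), and asic4, another acid-sensing channel family member (271 ± 102 against 665 ± 100.5). They included diras1b, a Ras-like GTPase (499 ± 93.7 against 830 ± 77.1), and prdx4, a peroxiredoxin of the endoplasmic reticulum (919 ± 30.9 against 2006 ± 797). kif5ab, a kinesin (119 ± 24.3 against 232 ± 48.2), carhsp1 (374 ± 21.3 against 640 ± 148), acsbg2, an acyl-CoA synthetase (151 ± 29.4 against 311 ± 94.0), and crhbp, which binds corticotropin-releasing hormone (9026 ± 1505 against 16587 ± 4403), completed the 8 on that side.

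Steroid-related genes deposited for the pituitary had higher values in dominant males in 3 of 3, with 0 adjusted over the list alone by limma (2 had an unadjusted p under 0.05). These were cyp19a1b, the brain-type aromatase (3867 ± 1830 against 1855 ± 700.2), pgr, the progesterone receptor (125 ± 57.4 against 49.3 ± 2.70), and hsd3b1 (769 ± 245 against 528 ± 61.0). In the growth axis, igfbp5 and igfbp4 (140 ± 37.9 against 80.8 ± 6.98) were higher and irs2, an insulin receptor substrate, was lower (368 ± 12.5 against 562 ± 122). All 3 passed adjusted over the list alone, among genes already selected by the authors' p-values. Genes typical of pineal and retina were also among the deposited rows, and both had higher values in dominant pituitaries. tph1, a tryptophan hydroxylase, stood at 672, 1802 and 892 reads against 89.7, 54.9 and 401. pde6hb, a photoreceptor phosphodiesterase subunit, stood at 4119, 17235 and 5291 against 1259, 3500 and 123. Both passed adjusted over the list alone, after the same selection.

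Further members of the lists were few. Each had been deposited for the authors' p under 0.05 on the same samples, so whether it passed here was largely set by that selection, and in a list with 1 deposited member nothing is adjusted. Higher adjusted over the list alone by limma were tph1 in the monoamine list (1 of 2), slc17a6 (1 of 1 neuronal), and cldn11a (1 of 2 myelin). So were cyp19a1b (1 of 1 radial glia), pdgfrb (1 of 1 endothelium and mural), col12a1a (1 of 1 fibroblast), col9a1b (1 of 1 cartilage), oxt (1 of 1 reproductive neuropeptide) and kcnj15 among 3 ion channels, of which kcnc2 was lower. crhbp, lower, was the 1 of 2 feeding and stress genes that passed so. No member passed so among 3 gonadotropin second messenger genes, 3 erythrocyte genes, 2 immediate early genes, 2 heat shock genes, 1 cholesterol gene and 3 genes of oxidative phosphorylation (unadjusted p under 0.05 for 2, 1, 0, 0, 0 and 1). The lists of pituitary receptors, clock, microglia, antiviral, skeletal muscle, cell cycle, lipid transport, glycolysis and ribosomal genes had 0 members deposited.

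Brain and pituitary differences were then compared gene by gene within each tissue's own fit. LOC100703972, LOC100703705 and lnpk were higher in dominant males in both tissues, and these were the 3 genes called in both. LOC100703972 and LOC100703705 are neighbours in the dense run of genes described below, where inherited haplotypes are a candidate, so they may not be separate signals. LOC100703972 differed by 3.54 ± 0.13 in the brain and 3.78 ± 0.32 in the pituitary, LOC100703705 by 3.23 ± 0.21 and 3.65 ± 0.49, and lnpk by 1.15 ± 0.10 and 2.29 ± 0.25. oxt differed in the same direction in both tissues but passed in neither. Whether its pituitary reads came from brain tissue carried along with the pituitaries was not tested. In contrast, fshb, lhb and cga were higher in dominant pituitaries and lower in dominant brains, where subordinate replicate 3 held the highest values.

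Of 685 pituitary genes also tested in the brain, 422 (61.6%) had the same sign. Of the 78 with an unadjusted p under 0.05 in the brain, 62 had the same sign (48 higher, 14 lower) and 16 the opposite. Across these genes, which are not independent replicates, Pearson's r was 0.429 and Spearman's rho 0.277. No gene passed a test of the difference between the tissues that takes them as independent (0 of 685 by limma estimates, with 181 at an unadjusted p under 0.05). The smallest adjusted p was 0.0817, for igfbp5. Each pituitary library, however, deviated most like the brain library of its own number and status (correlations of 0.186 to 0.582), so the tissues and their agreement cannot be taken as independent. With such samples paired, an alternative added after the data were seen, 5 of 685 genes passed by limma, all with a more positive difference in the pituitary. They included lhb and igfbp5 (adjusted p = 0.0369 for each) and cdc42ep1b (adjusted p = 0.0387). Pituitary genes were deposited by outcome, which favours large differences there. Of the 3 genes called in both, 0 remained without dominant replicate 3 and 2 without subordinate replicate 1, and 1 remained without each of the 4 other samples.

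**Figure D4:**
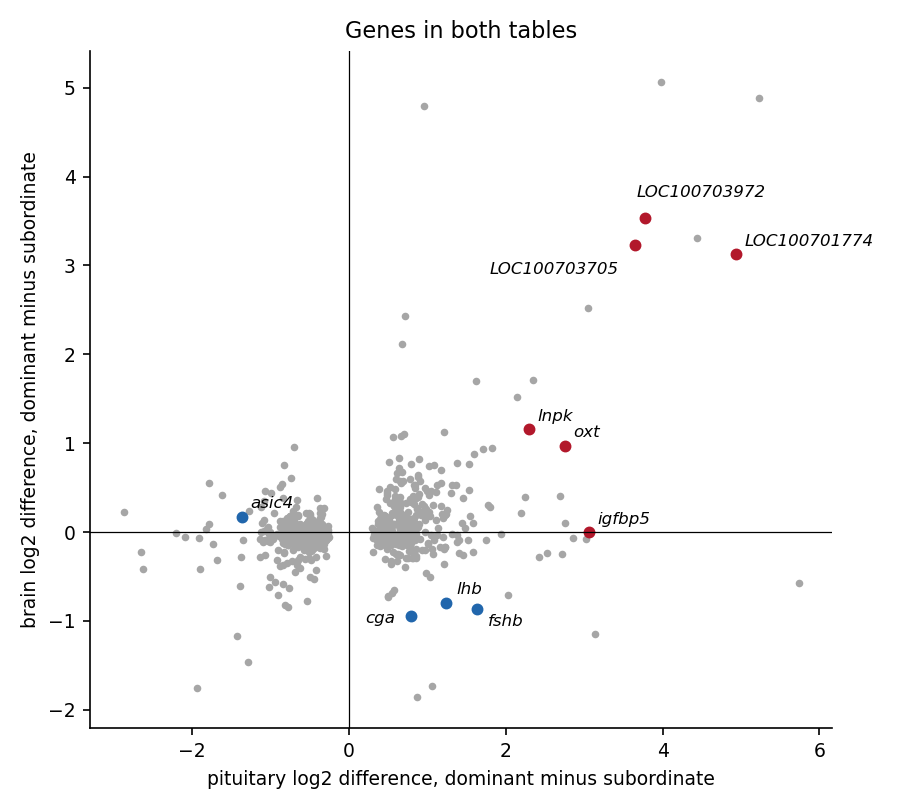
Log2 difference (dominant minus subordinate) in the pituitary (horizontal axis) and in the brain (vertical axis) for the 685 genes tested in both. Named red points share a direction in both tissues and named blue points differ, with LOC100703972, LOC100703705 and lnpk to the upper right and fshb, lhb and cga below 0 in the brain.

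The fold changes in the authors' deposited table were set against those fitted here. For the brain they had a Pearson r of 0.900 and a Spearman rho of 0.975 across 21743 genes against the authors' deposited table, with 558 genes of opposite sign. For the pituitary r was 0.974 and rho 0.997 against the authors' deposited table, with 0 of opposite sign. A p under 0.05 was given to 1058 brain genes (3.90%), 624 higher and 434 lower, in the authors' deposited table. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 81 brain genes, which included the 6 called here.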

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

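Every test in this part was chosen after the result was seen, except the tests of single genes within a tissue, the unpaired test between the tissues, the list tests without a covariate, the splits for the gene lists and for genes called in both tissues, and the test of the cholesterol list with a myelin covariate.

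Among the named genes, 4 had higher values in dominant males in one tissue and lower values in the other, with every dominant sample on one side of every subordinate sample in each. None of the 4 passed in either tissue (limma adjusted p = 0.934 in the brain and 0.0855 in the pituitary), and the brain difference of asic4 was 0.17. Genes outside the naming rule were not searched for this, and 16 of the 685 shared genes had opposite signs with an unadjusted p under 0.05 in the brain. The difference of log2 differences, pituitary minus brain, was 2.51 for fshb, 2.04 for lhb, 1.74 for cga and -1.54 for asic4. The tested difference did not pass adjustment over the 685 shared genes (limma adjusted p = 0.163 for each) with the tissues taken as independent. With samples of the same number and status paired, lhb passed (adjusted p = 0.0369), and asic4, cga and fshb did not (adjusted p = 0.0628 to 0.0933).

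Pituitary hormone transcripts were lower in dominant brains, which is the brain side of the gonadotropin difference. Equal carry-over of pituitary tissue in all brains would have made fshb, lhb and cga higher in dominant brains, and the tables argue against it, since their median difference in the brain was -0.87 and the groups of each did not overlap. More pituitary tissue left on the brain of subordinate replicate 3 may account for much of it, because all 7 members and gh1 were highest there and the list median moved from -0.56 to -0.195 without that library. Without it 7 of 7 members were still lower, and the list passed at camera's preset correlation (adjusted p = 0.00666) but not with an estimated correlation (adjusted p = 0.485, and 0.548 with all 6 libraries), so whether that library is the whole of the pattern stays open. With the hox score as a covariate the call ended (camera adjusted p = 0.681), as the mean difference went from -0.63 ± 0.40 (SE) to -0.21 ± 0.79, smaller and with a wider error. A difference of hormone expression in the brain itself stays open and was not tested.

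The genes that differed most in the brain lie beside each other. Of the 6 called genes 5 fall within 27 neighbouring places, and the densest run of 50 tested genes held 16 of the 1000 genes of smallest p, where shuffled places gave a median of 9. Placement at random is argued against (permutation p = 1e-04, the smallest the shuffles can give). The same run held 6 deposited pituitary genes, where 1.6 would be expected if tissue and place were unrelated. All 6 had the same sign in both tissues. The run and the pituitary genes were both picked by the same comparison, and the tissues are not independent, so this adds no separate support. Inherited haplotypes that differ between the few fish are a candidate explanation. Of the 9 other splits of the same brains, which do not follow status, 8 also gave runs denser than 95% of shuffles. The shuffles take neighbours as otherwise unrelated, so neighbours that vary together for another reason, such as loci that share reads, would do the same. The splits therefore do not single out haplotypes. Regulation of a block of neighbours with status cannot be told apart from haplotypes, because fish and status are the same split. Another split held a run of 26.

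In dominant brains 11 of 11 posterior hox genes, 19 of 21 myelin genes and 26 of 29 cholesterol genes were higher, although no posterior hox gene passed by limma (8 had an unadjusted p under 0.05) and both list calls are lost with an estimated correlation (adjusted p = 0.468 and 0.302). More hindmost brain or spinal cord in the dominant samples may explain the hox difference, which grew with the paralog group number (Spearman rho 0.738 over 22 genes). The one-sided permutation p of 1e-04, the smallest the shuffles can give, takes genes of the same 6 libraries as independent. It says nothing about the spread between fish, and the posterior genes were chosen after their values were seen. The hox score of subordinate brain 1 was 5.39, near the lowest dominant score of 6.32, against 1.69 and 2.67 in the other subordinate brains. For the myelin list more hindmost tissue is a candidate too, as the list median was 0.00501 with the hox score as a covariate. The mean difference then went from 0.25 ± 0.14 (SE) to -0.062 ± 0.21, so the call ended with a smaller difference and a wider error. For the cholesterol list it cannot be told apart from a change within cells, since the median kept 0.157 of 0.275 with the hox covariate (mean 0.28 ± 0.16 SE, from 0.37 ± 0.081). More myelin-forming cells, as the whole of the cholesterol difference or a part of it, stay open by the bound set beforehand. With a myelin score as a covariate the median was 0.188, which fell below that bound. The mean was then 0.264 ± 0.0792 (SE) and the camera adjusted p at the preset correlation 1.15e-06. By the mean and its error, a criterion chosen after the values were seen, a remainder stayed above 0, which over 6 libraries does not decide it. Status itself stays open for each list, because hox scores and status go together in these 6 brains.

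With 3 against 3 samples there are 10 splits, too few for a share under 0.05. In the brain 4 of the 10 splits, the real one included, gave at least 6 called genes, and the highest other split gave 7. For the lists the real split gave 12 and the others gave 3 to 8, so 1 of the 10 splits was as large. The pituitary genes had been selected by the real split, so 3 further counts decide nothing. These were the pituitary calls (6 and 0), the genes called in both tissues (3 and 0, as no other split called a pituitary gene) and the correlation of the tissues' differences (0.429 and 0.299), each with 1 of the 10 splits as large.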

How the results depend on the processing

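The hox covariate, the pairing of tissues and the adjustments of the authors' p-values were chosen after seeing the data. In the brain, where 6 genes passed, the replicate block left 1, leaving out a replicate gave 1 to 15, DESeq2 84, Benjamini-Hochberg adjustment of the authors' deposited p-values 81, and the hox score as a covariate 0. In the pituitary leaving out a replicate gave 0 to 255, DESeq2 190, adjusted p under 0.1 607, and the authors' deposited p-values adjusted as if 27115 genes had been tested 34. Genes called in both tissues came to 1 with the replicate block and 0 to 4 with a replicate left out, of which 0 to 2 were among the 3. Genes whose difference differs between the tissues came to 5, from 0, with brain and pituitary samples of the same number and status paired. Of the 12 lists 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), 0 with fry (3 of all 30 lists at an unadjusted p under 0.05), 5 with the hox covariate (the cell cycle list on the opposite side) and 6 to 9 with a replicate left out, where 6 to 10 lists passed in all. With the hox covariate the medians of the microglia, cell cycle and reproductive neuropeptide lists turned to -0.304, -0.391 and -0.0638. Over the left-out replicates the ribosomal median ran from -0.0115 to 0.0806, the microglia median from 0.0128 to 0.457 and the cell cycle median from 0.0842 to 0.402. The call was lost in 3, 3 and 4 of these 6 fits, in 5 for oxidative phosphorylation (median -0.0551 to -0.0161) and in 3 for immediate early genes (-0.4 to -0.0531). It was lost in 2 for the radial glia (0.0692 to 0.243) and matrix lists (0.0918 to 0.172), in 1 for reproductive neuropeptides and in 0 for the other 4 lists, where the median ran from 0.115 to 0.457 for myelin, 0.204 to 0.511 for antiviral, 0.228 to 0.321 for cholesterol and -0.749 to -0.195 for pituitary hormone genes. Uncalled genes changed sign when a replicate was left out, avp from -0.223 to 0.855, pdyn from -0.378 to 0.036, gal from -0.151 to 0.439, spx from -0.0861 to 0.475 and kiss2 from -0.0178 to 0.896, and gal gave -0.01 with edgeR and -0.0117 with DESeq2. Against the authors' deposited table r was 0.9299 in the brain and 0.9771 in the pituitary without a pseudocount and only over genes above 0 in all samples, which changes both the scale and the genes. Fewer samples stand behind the left-out fits, and otherwise the cause was not tested. The other settings kept these counts within 1.5 times, but of the 6 genes called in the pituitary with the replicate block (5 higher, 1 lower) only 4 were among the 6 called without it. For single named genes, 596 of 632 values in the brain and 300 of 352 in the pituitary kept their direction and their side of the threshold. Most of these genes were not called, and a gene that stayed uncalled counts as kept, so these shares say little about the calls. A call was lost in 13 values in the brain, 10 of them with a replicate left out. In the pituitary it was lost in 16, of which 14 had a replicate left out. Same-numbered dominant and subordinate samples showed little shared deviation (r 0.0916, -0.0303 and -0.0209 in the brain, 0.148, 0.0777 and -0.0527 in the pituitary). A sample correlated best with its own number for number 1 only. Deviations from means of 3 samples cannot exclude a shared tank, and the labels do not give tanks, so a pairing stays open. The pituitary list alternatives were not run, because that table is a selection. Depth beyond its 714 genes is unknown.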

Other observations

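Genes of the secretory pathway were among the deposited pituitary genes. All 26 of a list written after the table was seen had lower values in dominant males, and as the list was written from the table, this count tests nothing. For 19 of the 26 the groups did not overlap, where 471 of all 714 deposited genes (66.0%) had such groups. By limma 0 passed over the 714 genes (median log2 difference -0.41). scg2b, a secretogranin of hormone granules, stood at 11009 ± 2062 against 17807 ± 3112 (n = 3), cpe, which trims prohormones, at 22122 ± 2162 against 28064 ± 3140, and scg3 at 31693 ± 2614 against 39521 ± 1805. tram1 and ddost, which act at the translocon, stood at 1090 ± 109 against 1613 ± 281 and 2711 ± 233 against 3516 ± 538, and tmed2 and tmed10, of early secretory vesicles, at 1407 ± 201 against 2080 ± 397 and 4857 ± 146 against 6025 ± 455.

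Across tissues each pituitary library deviated most like the brain library of its own number and status, with correlations over genes of 0.582, 0.441 and 0.503 in dominant males and 0.186, 0.241 and 0.201 in subordinate males. The labels do not say whether such a pair came from the same fish.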
